A study of Homo sapiens with 3 samples.

How the data were processed

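CTCF-bound DNA was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in COLO829, an established malignant melanoma cell line. CTCF is a zinc finger protein that binds DNA and, together with the cohesin complex, shapes chromatin loops and insulates neighbouring domains. Per the labels' protocols, cells were cross-linked in 1% formaldehyde, nuclei were sonicated for 6 hours, and the chromatin was split between an antibody against CTCF and rabbit immunoglobulin G (IgG), which measures background. The series holds 3 samples, namely 2 CTCF immunoprecipitations, labelled replicates 1 and 2, and 1 IgG immunoprecipitation. Per the series' design text, the CTCF replicates came from 2 replicate experiments that were sequenced separately, and the IgG library came from the second experiment.

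The authors deposited 1 list of peaks for each CTCF sample. Each list gives a chromosome, a start and an end per peak, and no other value such as a score, a height, a p-value or a strand. Per the submitters' processing notes, BWA 0.7.5a-r405 and HOMER were used and the genome build was hg19. The peak caller's settings, its thresholds and whether the IgG library entered the peak calls are not given in the sources used here. All peaks of a list have the same width, which is 332 bp in replicate 1 and 338 bp in replicate 2, so a peak's width carries no information on its strength. No 2 peaks of 1 list have centres closer than 656 bp in replicate 1 and 693 bp in replicate 2, which are 1.98 and 2.05 peak widths, so neighbouring sites at shorter distances were not listed separately. The lists give no read counts, so sequencing depth and signal per peak are unknown, and no interval that needs depth could be given. The IgG library was not analysed here, so the background at each peak is not reported.

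Peaks were counted as shared when a peak of the other list overlapped by at least 1 bp. The count was checked with bedtools 2.31.1 and was identical. Overlap was compared with 100 random placements of the other list within the same chromosomes, keeping peak widths and the number of peaks per chromosome. The smallest one-sided p that 100 placements can give is 0.0099. For overlap, clusters and 1 Mb windows, placements covered the span from the first to the last peak of a chromosome, assembly gaps included, or, where stated, moved each peak by at most 100 kb. For the local density of single-replicate peaks, placements within that span left out stretches over 3 Mb without a peak. For chromosome starts, placements ran from the first coordinate of each chromosome. Chromosomes with at least 50 peaks in total were compared by a chi-square test of replicate against chromosome. Densities are peaks per Mb of the span from the first to the last peak of a chromosome. Intervals on counts are exact 95% Poisson intervals and intervals on shares are exact (Clopper-Pearson) 95% binomial intervals, and both cover counting error only.

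The overlap test with placements over the whole span and the chi-square test of the complete lists were fixed before the data were examined. Placements that moved each peak by at most 100 kb, the chi-square test of single-replicate peaks and the analyses of clusters, of 1 Mb windows, of chromosome starts and ends and of the regions around single-replicate peaks were chosen after the lists had been seen. The number of shared peaks within 500 kb of each single-replicate peak was taken as its local density. Its median was compared between the replicates within each chromosome, with a two-sided sign-flip permutation test over chromosomes (100000 resamples). Clusters were runs of shared peaks whose neighbouring centres lay at most 10 kb apart. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. On simulated lists in which 89.9% of the 46966 peaks were kept, 90.0% were recovered as shared, and with none kept 1.02% were. Kept peaks were moved by much less than a peak width, so each still overlapped its source. This check tried the counting and not the overlap rule at the offsets seen in the data. On 9000 simulated single-replicate peaks, an unbiased draw gave a permutation p of 0.864 in the density test. A draw weighted towards dense regions gave a permutation p of 2.0e-05. The weighted draw had a difference of 3.52 sites, against 1.57 in the data, so the test was not tried at the observed size.

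The plan also held comparisons of peak scores, of the CTCF sequence motif, of motif orientation, of dipyrimidine content across the motif, of genomic annotation and of gene lists at promoters, and it named genes by peak score and by promoter peaks. The lists carry no scores, and no hg19 sequence or annotation was used here, so these comparisons were not made, and peaks are named by hg19 coordinates (1-based) instead of by gene. The gene lists fixed for this purpose covered melanocyte lineage, melanoma drivers, nucleotide excision repair, CTCF and cohesin, imprinted and insulator loci, clustered protocadherins, HOX genes, B lymphoid, fibroblast and keratinocyte markers and ribosomal protein genes, and none of them was tested. The regions named in the text were chosen by their number of shared peaks. The p-values treat peaks or chromosomes as units and describe these lists from 1 cell line.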

Results

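CTCF binding was mapped in COLO829 melanoma cells in 2 replicate experiments, as part of a study of mutations at CTCF and cohesin binding sites and of nucleotide excision repair across the CTCF motif. The question addressed by the binding data was where CTCF sits in the genome of these cells. Replicate 1 gave 46966 peaks that covered 15.6 Mb, and replicate 2 gave 50338 peaks that covered 17.0 Mb. The median distance between the centres of neighbouring peaks was 32.7 kb in replicate 1 (interquartile range 12.9 to 75.3 kb) and 30.2 kb in replicate 2 (12.2 to 69.1 kb). The 1 IgG sample of the series was not analysed here. The depth behind each peak is unknown, because the lists hold positions only.

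Most CTCF sites were found in both experiments. Of the replicate 1 peaks, 44050 (93.8%) overlapped a replicate 2 peak, and the same number of replicate 2 peaks (87.5%) overlapped a replicate 1 peak. Each of the 44050 pairs was one to one, which the peak widths and the minimum spacing of listed peaks all but require. The lists together held 53254 sites, of which 82.7% were in both replicates, 2916 in replicate 1 alone and 6288 in replicate 2 alone. Random placements of replicate 2 peaks on the same chromosomes overlapped 1.18% ± 0.05 of the replicate 1 peaks (SD over 100 placements, highest 1.30%). Random placements of replicate 1 peaks overlapped 1.11% ± 0.05 of the replicate 2 peaks (highest 1.23%). None of the 100 placements reached the observed overlap in either direction, which gave p = 0.0099 in a one-sided permutation of positions, the smallest value that 100 placements allow. When each peak was moved by at most 100 kb, a setting added after the lists had been seen which keeps the regional density of sites, the mean overlap by chance was 1.87% of the replicate 1 peaks and 1.75% of the replicate 2 peaks. These shares measure how often the lists coincide and give no estimate of how often a peak is bound. Random positions are a weak background, so the test does not show that the shared peaks are bound by CTCF.

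The position of a shared site was nearly the same in both experiments. The centres of a pair lay a median of 14 bp apart (interquartile range 6 to 26 bp), and 95% of the pairs lay within 59 bp. In 28859 pairs (65.5%) the distance was at most 20 bp, and in 933 pairs (2.12%) the centres were identical. The signed offset, replicate 2 minus replicate 1, had a mean of 0.12 bp and an SD of 29.6 bp over the 44050 pairs. In 486 pairs (1.10%) the centres were more than 100 bp apart.

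**Figure D1:**
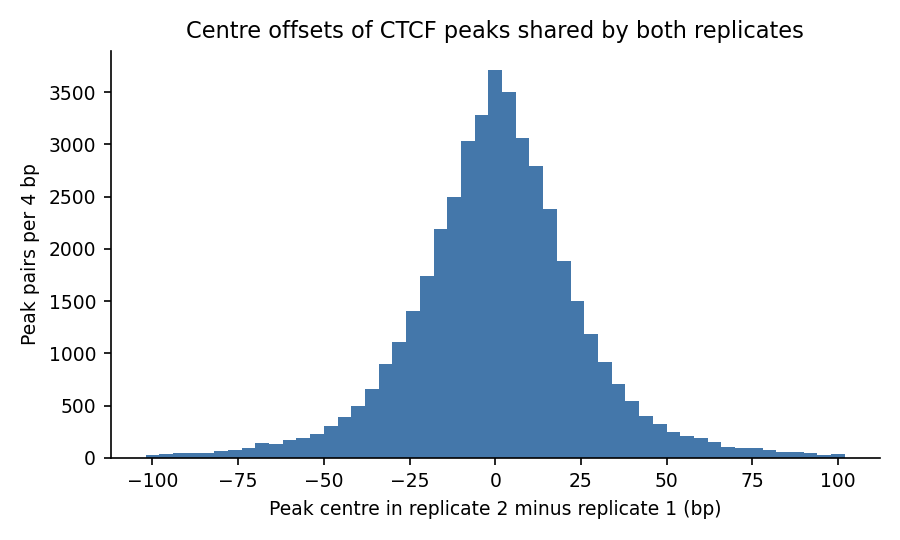
Distance between the peak centres of each shared CTCF site, in bp (replicate 2 minus replicate 1, x axis), against the number of peak pairs per 4 bp (y axis); offsets beyond the plotted range are left out. The offsets centre on 0, with a median absolute distance of 14 bp over all 44050 pairs.

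CTCF sites were unevenly spread over the chromosomes. Shared sites were densest on chromosome 19, with 26.6 per Mb (95% Poisson interval 25.3 to 28.0), followed by chromosome 22 with 25.2 per Mb (23.6 to 26.9) and chromosome 17 with 23.5 per Mb (22.4 to 24.6). Chromosomes 17, 19 and 22 are known as gene-rich chromosomes. The lowest density was on chromosome X, with 11.0 per Mb (10.5 to 11.5), and chromosome 5 had 11.8 per Mb (11.3 to 12.3). Chromosomes 4 and 18 both had 12.0 per Mb, with intervals of 11.5 to 12.5 and 11.2 to 12.8. The highest density was 2.43 times the lowest, and the median over 23 chromosomes was 14.6 per Mb. Chromosome Y had fewer than 50 peaks and was left out. Spans include stretches without a peak, which lowers the densities of chromosomes 1, 9 and 16, where the longest lay. The copy number of each chromosome in these cells was not measured here.

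The distribution of peaks over the 23 chromosomes did not differ detectably between the complete lists (chi-square 7.11, 22 degrees of freedom, p = 0.999). The shared sites are counted in both lists, which makes this test insensitive. The share of replicate 1 peaks found again in replicate 2 ranged from 91.3% on chromosome 4 to 96.1% on chromosome 16. The share of replicate 2 peaks found again in replicate 1 ranged from 85.4% on chromosome 18 to 90.2% on chromosome X. Among the single-replicate peaks alone, a comparison added after the lists had been seen, the balance between the replicates did differ by chromosome (chi-square 106, 22 degrees of freedom, p = 5.48e-13). Replicate 2 held 2.16 times as many of them as replicate 1 in total, and it contributed more of them on all 23 chromosomes. Its share was lowest on chromosome X, at 61.1% (95% binomial interval 55.3 to 66.6%), and on chromosome 4, at 61.1% (57.0 to 65.2%). It was highest on chromosome 16, at 79.2% (73.9 to 84.0%), and on chromosome 19, at 77.6% (72.4 to 82.1%).

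**Figure D2:**
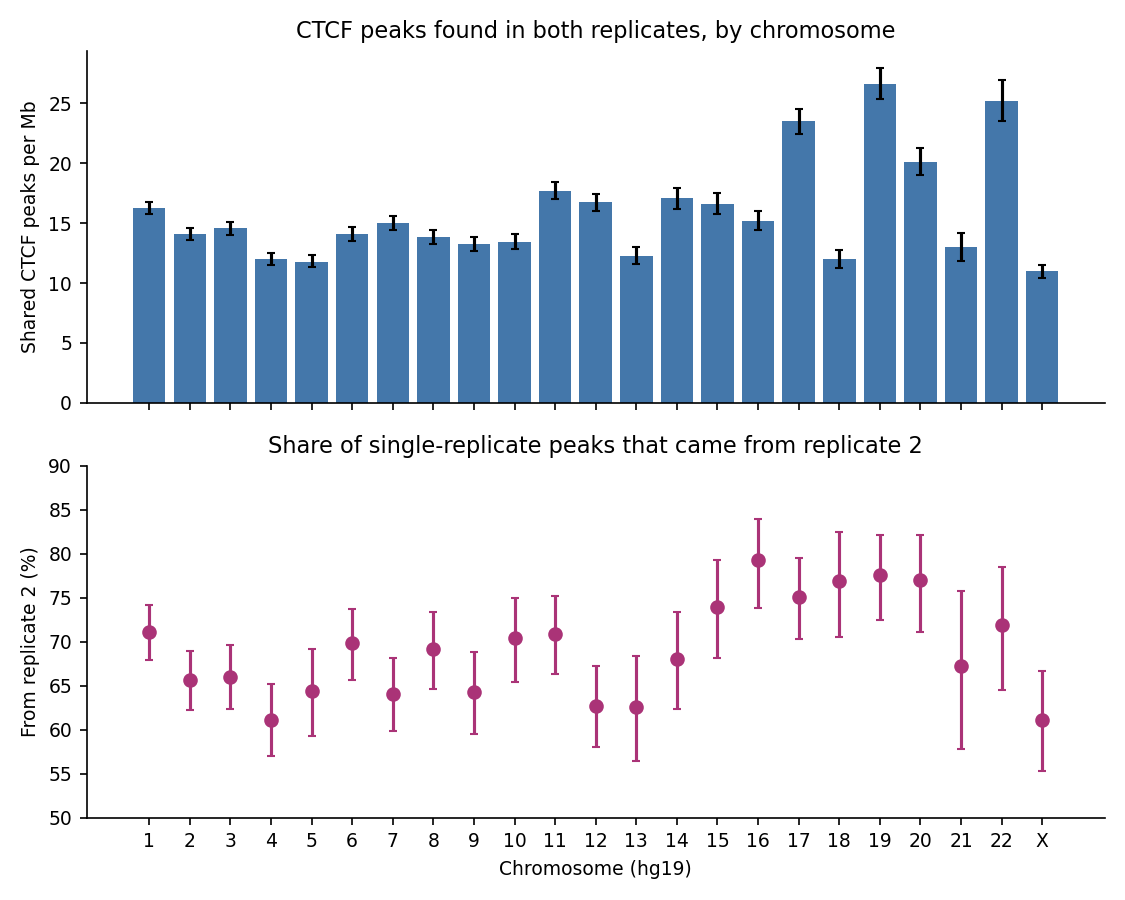
Upper panel, CTCF peaks found in both replicates per Mb of each chromosome, with exact 95% Poisson intervals; lower panel, the percentage of single-replicate peaks that came from replicate 2, with exact 95% binomial intervals and an axis that starts at 50%. Chromosomes 17, 19 and 22 have the most shared peaks per Mb, and the replicate 2 share runs from 61.1% on chromosome X to 79.2% on chromosome 16.

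Shared sites were also gathered in particular regions within chromosomes. In total 14857 shared sites (33.7%) had another shared site within 10 kb, against 26.7% ± 0.26 of randomly placed sites (SD over 100 placements, highest 27.3%, one-sided permutation p = 0.0099). They formed 6538 clusters, and the largest held 9 sites. The largest cluster in any random placement held 10, so the size of the largest clusters did not stand apart from chance at this limit. With a limit of 20 kb the largest held 17 sites, against 13 in any random placement. Random placements ignore the minimum spacing of listed peaks and can fall in assembly gaps, so they are an approximate background. One of the clusters of 9 sites lay on chromosome 5 from 140552012 to 140603017, and the other on chromosome 7 from 38375239 to 38414393. A cluster of 8 sites lay near the first, on chromosome 5 from 140699727 to 140739716. Clusters of 8 sites also lay on chromosome 12 from 49725419 to 49763995 and on chromosome 17 from 73743904 to 73779777. These 5 clusters contained no peak of replicate 1 alone. They contained no peak of replicate 2 alone either, except for 1 such peak in the chromosome 7 cluster.

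The 1 Mb window with the most shared sites was on chromosome 5, from 140000001 to 141000000, with 60 shared sites (95% Poisson interval 45.8 to 77.2). It held 62 peaks in each list. The next windows had 53 shared sites each and lay on chromosome 11 from 61000001 to 62000000, on chromosome 17 from 73000001 to 74000000, on chromosome 19 from 42000001 to 43000000 and on chromosome 9 from 139000001 to 140000000. The median over 2875 windows with at least 1 shared site was 14. The highest window in any of the 100 random placements held 50 sites, and 0 of the placements reached 60. The Poisson intervals of the leading windows overlap, so their order is not resolved.

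The longest stretches without a peak in either list lay on chromosome 1 from 121189509 to 142586205 (21.4 Mb), on chromosome 9 from 47204588 to 65613887 (18.4 Mb) and on chromosome 16 from 35143659 to 46516816 (11.4 Mb). There were 19 stretches over 3 Mb, on 19 different chromosomes. Assembly gaps and regions where reads cannot be placed were not annotated here, so a stretch without peaks does not show absence of CTCF.

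Peaks seen in replicate 1 alone made up a larger share of all sites where shared sites were sparse. The share of peaks seen in replicate 2 alone lay between 11.3% and 12.4% at every density. All sites on the 23 chromosomes were ranked by the number of shared sites within 500 kb and divided into 5 classes of 10649 sites. Peaks of replicate 1 alone made up 8.11% of the sites in the sparsest class (95% binomial interval 7.60 to 8.65%) and 3.98% in the densest (3.62 to 4.37%). Peaks of replicate 2 alone made up 11.5% in the sparsest class (10.9 to 12.1%) and 11.3% in the densest (10.7 to 11.9%). Shared sites both rank the classes and count among all sites, so a falling share does not mean fewer peaks per Mb. Peaks of replicate 1 alone had a mean of 17.3 shared sites within 500 kb, against 15.7 around randomly placed peaks (highest of 100 placements 16.0). The median number of shared sites within 500 kb was 16 around peaks of replicate 1 alone, 18 around peaks of replicate 2 alone and 18 around shared peaks. Within chromosomes, the median around replicate 2 peaks exceeded that around replicate 1 peaks by 1.57 sites on average (SD 1.38 over 23 chromosomes, higher on 19 and lower on 2, two-sided permutation p = 6.0e-05). Counting shared sites within 100 kb instead gave a difference of 0.26 sites that did not pass the test (permutation p = 0.106).

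**Figure D3:**
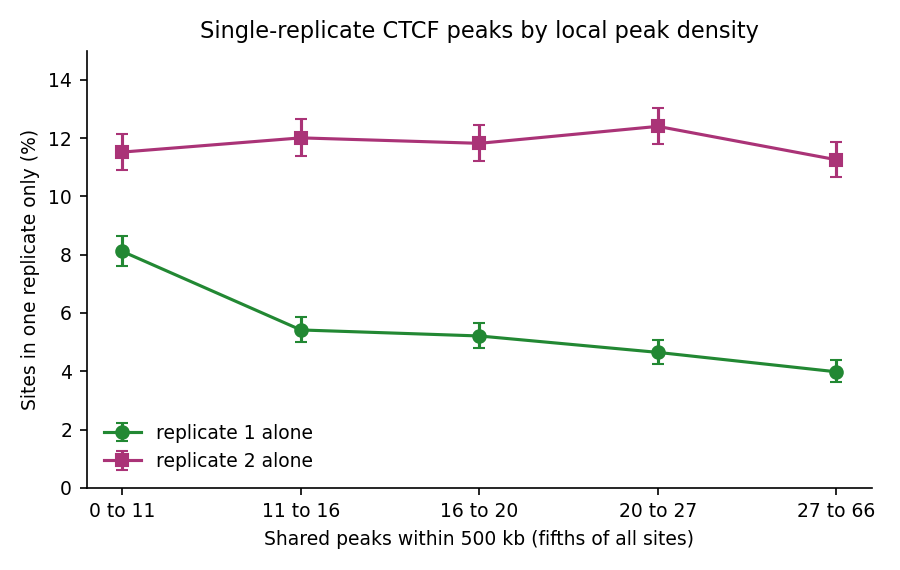
Percentage of all CTCF sites found in replicate 1 alone or in replicate 2 alone (y axis), in 5 classes of 10649 sites ranked by the number of shared peaks within 500 kb (x axis); bars are exact 95% binomial intervals. The replicate 1 share falls from 8.11% in the sparsest class to 3.98% in the densest, and the replicate 2 share is 11.5% in the sparsest and 11.3% in the densest.

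Some single-replicate peaks had a peak of the other list close by that did not overlap. A peak of replicate 2 lay within 1000 bp of 171 of the peaks of replicate 1 alone (5.86%, 95% binomial interval 5.04 to 6.78%). A peak of replicate 1 lay within 1000 bp of 170 of the peaks of replicate 2 alone (2.70%, 2.32 to 3.13%). In 91 cases in each list the close peak was itself found in its own replicate only. The median distance to the nearest peak of the other list was 16.9 kb for peaks of replicate 1 alone and 17.9 kb for peaks of replicate 2 alone.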

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

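The overlap of the lists exceeded every random placement under each alternative that was run. Lists from libraries of the same cell line would hardly fail this test, so passing it says little. It does not show that the shared peaks are bound by CTCF, since the motif and the IgG library were not examined. With at least 50% reciprocal overlap, centres within 100 bp, or autosomes only, 92.8% to 93.8% of the replicate 1 peaks and 86.5% to 87.4% of the replicate 2 peaks were shared. The chromosome distribution gave a chi-square of 6.08 with autosomes only (p = 0.999). Restricting the same test to single-replicate peaks, chosen after seeing the data, gave a chi-square of 106 (p = 5.48e-13), because the shared sites counted in both lists then drop out. Counted within 500 kb, the difference in local density lay between 1.43 and 1.61 sites with a 50% reciprocal overlap, autosomes only, chromosome ends left out, or replicate 2 peaks within 1000 bp of replicate 1 left out. Leaving out near neighbours within 5000 bp from both lists gave 2.13 sites, but that filter leaves 2335 of 2916 replicate 1 peaks against 5446 of 6288 replicate 2 peaks and can raise the difference by itself. Counted within 2000 kb, where the medians were 60 and 67 sites, the difference was 5.07 sites, and counted within 100 kb, where they were 3 and 4, it was 0.26 sites and did not pass the test (permutation p = 0.106). The share of sites in clusters was 15.6% with a limit of 5 kb (mean by chance 14.4%) and 55.9% with a limit of 20 kb (45.9%). From 1 list alone it was 35.0% for replicate 1 (28.0%) and 36.2% for replicate 2 (29.8%). Each share was above its highest random placement, but the excess at 5 kb was small (highest placement 14.9%). Placements could fall in long stretches without a peak, which lowers the share by chance, and ignored the minimum spacing, which can raise it. The excess at 5 kb is therefore not firm. The largest cluster at 5 kb held 7 sites, as did the largest by chance. Leaving out a replicate gives no overlap, so that value has no such alternative. Settings that rank peaks by score, and those for scores, motif, orientation, dipyrimidines, annotation and gene lists, were not run, since scores and an hg19 sequence and annotation were not used here. No paired analysis was possible because the series has 1 IgG sample, so at most 1 pair with a CTCF replicate could be formed. Without read depth, a peak missing from 1 list cannot be separated into an unbound site and an undetected one.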

Other observations

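The tests of the balance between single-replicate peaks and of chromosome starts were chosen after the lists had been seen. For the balance, what each explanation predicts was written before its own result, except for the test of minimum spacing.

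The list with fewer peaks, replicate 1, still held 2916 sites that replicate 2 did not. Over 23 chromosomes, the log2 ratio of peaks in replicate 2 alone to peaks in replicate 1 alone rose with the density of shared sites (Pearson's r = 0.57, permutation p = 0.0040; Spearman's rho = 0.60, permutation p = 0.0032). Without chromosomes 19 and 22, the farthest from the median density, r was 0.52 (permutation p = 0.016). Chromosomes 16 and 18 had high shares from replicate 2 without a high density, with 79.2% of the single-replicate peaks at 15.2 shared sites per Mb and 76.9% at 12.0 shared sites per Mb. The span of chromosome 16 includes a stretch of 11.4 Mb without a peak, which lowers its density. Within 5 Mb of the first or last peak of a chromosome lay 12.9% of the peaks of replicate 2 alone (95% binomial interval 12.1 to 13.8%), 8.51% of the peaks of replicate 1 alone (7.52 to 9.58%) and 10.5% of shared peaks (10.2 to 10.8%). The odds ratio between the replicates was 1.60 (Fisher's exact test, two-sided, p = 3.03e-10). This test pooled the chromosomes, which differ in length and in the balance between the replicates, and took peaks as independent. The odds ratio is therefore not an effect of chromosome ends alone.

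The pattern of most interest is that peaks of replicate 1 alone lie in regions with fewer shared sites than peaks of replicate 2 alone. The minimum spacing of listed peaks is argued against as the whole cause by the few peaks it could concern. Of the 6288 peaks of replicate 2 alone, 170 lay within 1000 bp of a replicate 1 peak. The within-chromosome difference was 1.54 sites (permutation p = 6.0e-05) when these were left out and all peaks of replicate 1 alone were kept. Leaving out so few could hardly change a difference of medians, so this p adds little. Chromosome ends are argued against as the whole cause, since the difference was 1.61 sites (permutation p = 2.0e-05) without them. Peaks of replicate 1 alone had a mean of 17.3 shared sites within 500 kb, above the highest of 100 random placements (16.0). This argues against background calls scattered evenly over the genome as the source of all these peaks. The placements could still fall in assembly gaps shorter than 3 Mb, which can lower their mean, so the margin is approximate. The mean was 19.4 around peaks of replicate 2 alone and 19.7 around shared peaks, so a scattered part of the replicate 1 peaks remains open. A candidate explanation is a base composition bias that differed between the libraries, which could favour GC-rich, site-dense regions in one of them. Base composition was not measured here, and the correlation of 0.57 over chromosomes only restates the pattern. This explanation cannot be told apart from a difference in the chromatin of the cultures. Nor can it be told apart from a difference in sequencing depth or in peak calling, which are not known here. No biological explanation was tested, because the replicates are of 1 group.

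In both lists, 8 shared peaks on 6 chromosomes lay within 20 kb of the start of a chromosome's coordinates, the nearest at 11231 to 11562 on chromosome 9 in replicate 1. Of 100 random placements, 35 put as many there, but 92.0% of the peaks placed there fell before the first listed peak of their chromosome, where sequence can be missing, so this test decides nothing about chance.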
